A study of Rattus norvegicus with 6 samples.

How the data were processed

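Total RNA from rat brain tissue was hybridized to 6 Agilent single-channel rat arrays, 3 sham and 3 ICH, 1 array per sample. Per the labels' protocols, RNA was prepared with TRIzol and labelled with Cy3 through linear amplification. The series design text speaks of transfected replicates for the ICH group; no other label does, and the groups were taken from the sample titles. How the hemorrhage was made, and how the tissue was dissected, is not given in the sources used here.

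Per the file headers, the intensity values were read with Agilent Feature Extraction 11.5.1.1, background-subtracted and detrended within each array, and not normalized between arrays. The submitters' processing notes name version 10.7 of the same program. Per the file headers, the flags used here, with the value 0 or 1 for each spot, mark spots well above background, saturated or not uniform. The deposited table holds log2 values that equal, within 0.001 for 98.3% to 99.2% of probes, the mean over a probe's spots of the log2 intensity minus the 75th percentile of the array; the notes do not state this step, which was worked out from the values.

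For the tests, control spots were left out, spots with a non-uniformity mark (1 to 9 per array) were set to missing, log2 intensity was centred on the 75th percentile of each array, and the spots of a probe were averaged. A probe counted as well above background on an array if at least 0.5 of its spots did, and probes were kept if they did so on at least 3 of the 6 arrays. Another 4 probes with a missing value were left out. Probe accessions were matched to the RefSeq gene table of assembly GRCr8, used for names only: 18355 of 30367 probes had 1 symbol, 0 had several and 12012 had none. For each symbol the probe with the highest mean was used, and probes without a symbol stayed as they were, which gave 22179 rows.

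Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, 6.12 degrees of freedom), with Benjamini-Hochberg adjustment over all rows. Gene lists were tested with camera of the same package, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. A list member counts as adjusted over the list alone where Benjamini-Hochberg was applied to its list's members only. Where a gene was not well above background on any array of a group, each value of that group was raised to the lowest value well above background on its array, which gives a bound on the fold change. Principal components were taken over the rows tested. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

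The 33 lists, with 696 symbols measured, covered responses (heme and iron handling; cytokines and chemokines; innate sensing, NF-kB and inflammasome; complement; interferon-stimulated genes; matrix, proteases and fibrinolysis) and further Nrf2 targets and metallothioneins, ER stress and amino acid response, heat shock proteins, cell death and p53, hypoxia and glycolysis, immediate early genes, cell cycle, cholesterol synthesis, ion and water transport, and glutamate and GABA signalling. Lists for cell types covered neurons, striatal and cortical projection neurons, thalamic neurons, oligodendrocytes, their precursors, homeostatic and reactive astrocytes, homeostatic microglia, activated myeloid cells and monocytes, neutrophils, lymphocytes, erythroid cells, endothelium and barrier, mural cells, meninges and fibroblasts, and choroid plexus and ependyma. A list of hippocampal markers was added later, before its values were seen.

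Genes were to be named if called with the largest differences, or with the largest bounds, and for each list the 2 called members with the largest difference; where a list had no called member, the 2 with the highest mean. As 0 genes were called, only the last part of the rule applied. Some members that it would name are not reported here.

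Alternatives set beforehand were normexp background correction (offset 50) on the median spot and background signals, quantile normalization, centring on the median, the deposited log2 values, no filter or a filter on all 6 arrays for dim probes, spots with marks kept, the mean of a gene's probes, an intensity trend with robust variance, the replicate number or the slide row as a block, leaving out each array, an estimated correlation between genes and the fry test. Normexp was to use the mean spot signal, which the files lack, so the median was used. Centring on spike-in probes and array quality weights were added after the data were examined. A block for the slide or the scan was not possible, as all arrays share 1 slide and 1 scan.

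The gene test was tested on simulated data with 200 changed genes in each of 10 runs on 22179 rows. For ICH minus sham it recovered 20.6% of genes changed 2-fold, 84.2% at 4-fold, 93.4% at 8-fold and 97.2% at 16-fold, with 5.14% false calls. Simulated values had the same spread in both groups, while the median standard deviation of a gene was 0.14 among sham and 0.31 among ICH arrays. The shares recovered therefore need not hold for the real arrays. A list shifted by −0.5 was called in 10 of 10 runs, and other lists in 0. The simulated genes were independent of each other, while the estimated correlation between genes was 0.73 in the innate sensing list. These runs therefore do not give the rate of false list calls in the real data.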

Results

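Transcript levels in rat brain tissue were measured on 6 single-channel arrays, 3 from sham-operated rats and 3 from rats with intracerebral hemorrhage (ICH), a bleed into the brain. The labels call the ICH tissue peripheral brain tissue, and the series title places it around the hematoma, the clot left by the bleed. All samples carry the label day 1, without saying from what the day is counted. The comparison asks which transcripts differ in tissue next to a hematoma. Each array held 58717 spots other than controls, for 30367 probes. The share of spots well above background was 83.6%, 84.1% and 83.4% on sham 1 to 3 and 85.4%, 81.8% and 82.8% on ICH 1 to 3, and 0 spots were saturated. The 75th percentile of the processed signal ran from 5726 to 6676, and the median coefficient of variation of replicate spots from 3.01% to 3.90%. The labels call the arrays of a group biological replicates, and 0 pairs of arrays held identical signals. The number of arrays, 3 per group, limits the precision. The test, the filters, the 33 gene lists and the rule for naming genes were chosen before the data were examined. Apart from the brightest 2 members of each list, the genes named here were chosen after their values were seen. Differences are log2 values, ICH minus sham, given ± SE where an error stands beside them, with n = 3 arrays in each group, and values per array are relative to the sham mean.

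The sham arrays lay close together and the ICH arrays did not. Correlations across genes were 0.985 to 0.991 within sham, 0.949 to 0.980 within ICH and 0.947 to 0.986 between the groups. The median standard deviation of a gene was 0.14 among sham arrays and 0.31 among ICH arrays. The first principal component held 52.7% of the variance, with ICH 2 at 102.1, ICH 1 at 10.2 and ICH 3 at −23.9, beside −33.2, −24.7 and −30.4 for sham 1 to 3. The second held 21.8%, with ICH 1 at −55.7, ICH 3 at −20.1 and ICH 2 at 18.7, against 4.84 to 40.5 for the sham arrays.

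**Figure D1:**
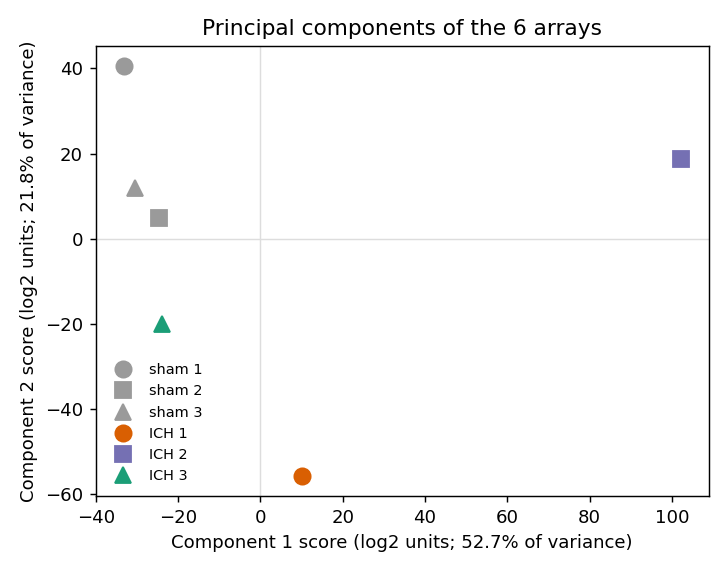
Scores of the 6 arrays on the first and second principal components of the normalized log2 values, with sham arrays in grey and each ICH array in its own colour. On the first component ICH 2 lies at 102.1, while ICH 3, at −23.9, lies within 1 unit of sham 2, at −24.7. On the second component ICH 3, at −20.1, lies below the sham arrays, at 4.84 to 40.5.

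Klk8, which encodes a secreted serine protease of the brain, was 71.8-fold higher in ICH (6.17 ± 0.41, adjusted p = 0.0533), at 6.27, 5.35 and 6.88 on ICH 1 to 3. The size of this difference depended on the background handling, and with normexp background correction it was 4.64. Neurod6, a transcription factor of forebrain excitatory neurons, was 4.13-fold higher (2.04 ± 0.16, adjusted p = 0.0823). Homer3, a scaffold protein of synapses, was higher by 1.69 ± 0.16, the ganglioside sialyltransferase gene St6galnac5 by 1.37 ± 0.12, the orphan receptor gene Gpr22 by 1.62 ± 0.15 and Foxp3, a transcription factor of regulatory T cells, by 1.91 ± 0.18, all at an adjusted p of 0.0914. Gabra5, a subunit of the GABA-A receptor, differed by 1.65 ± 0.17 (adjusted p = 0.114). In the other direction, the transcription factor gene Tfap2b differed by −2.51 ± 0.29 and Art3, of the ADP-ribosyltransferase family, by −1.11 ± 0.13, both at an adjusted p of 0.163, where another probe of Art3 gave −0.62. None of these passed: limma called 0 of the 22179 rows, 12963 of them with a gene symbol, at an adjusted p under 0.05, with or without a limit of 2-fold. At an unadjusted p under 0.05 there were 3265 rows, 1366 higher and 1899 lower, where chance gives 1109, and 103 rows had an unadjusted p under 0.001. Among gene symbols these were 913 higher and 949 lower. All 3 ICH values lay above all sham values in 2431 rows and below them in 3667, together 27.5% of rows, where chance gives 10%. Both chance figures are averages, and genes vary together across arrays, so a single grouping can lie far from them by chance.

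Several of the largest differences were seen on 2 of the ICH arrays more than on the other. Serpina3n, a protease inhibitor of reactive astrocytes, stood at 6.92, 8.40 and 2.14 on ICH 1 to 3 (adjusted p = 0.301), and the neutrophil attractant Cxcl2 at 6.49, 5.98 and 1.43 (adjusted p = 0.301). The non-coding RNA H19 stood at 4.54, 5.47 and 1.29, and Lcn2, which binds iron-carrying siderophores, at 4.78, 5.61 and 0.21. For genes not well above background on any sham array only a bound can be given, with each dim value raised to the lowest value well above background on its array. Kng2 and Kng1, which encode kininogens, the precursors of bradykinin, were at least 52.8-fold and 38.3-fold higher (adjusted p = 0.301 for both). Trem3, a receptor of myeloid cells, was at least 14.3-fold higher (adjusted p = 0.301), and Mmp9, a protease that degrades basement membrane, at least 13.8-fold (adjusted p = 0.179). These bounds for Kng2, Kng1, Trem3 and Mmp9 were 161-fold, 114-fold, 31.6-fold and 21.3-fold without ICH 3, and 16.7-fold, 12.3-fold, 8.48-fold and 10.2-fold without ICH 2. The other way round, Ces2b was at least 5.48-fold lower (adjusted p = 0.197) and the urea transporter gene Slc14a2 at least 4.96-fold lower (adjusted p = 0.301) on ICH arrays, where neither was well above background, and without sham 1 the bounds were 3.71-fold and 3.05-fold. The bound for Slc14a2 is that of the probe used, and another probe of the gene differed by −2.04. Among genes measured on all arrays, Npvf, a hypothalamic neuropeptide precursor, differed by −2.65 ± 0.61 (adjusted p = 0.301), and Cdhr1, a cadherin, by −2.13 ± 0.33 (adjusted p = 0.195).

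Single arrays decided how many genes passed. Without ICH 3, limma called 36 rows, 32 higher and 4 lower, among them Klk8, Neurod6, Serpina3n, Cxcl2, Lcn2, Mmp9, H19, Trem1, Trem3, Msr1, Cd14, Spp1 and the heme oxygenase gene Hmox1. Calcr, the calcitonin receptor gene, and the protocadherin gene Pcdhb6 were among those lower. Without ICH 2 it called 8, with Klk8 and the sphingomyelinase gene Smpd2 among 7 higher and the inflammasome sensor gene Nlrp1a the 1 lower. The rows at an unadjusted p under 0.05 dropped to 1346 without sham 1, 2012 without sham 2 and 1732 without sham 3, and those higher came to 683, 769 and 786, against 2135 without ICH 3. Those lower came to 663, 1243 and 946 without sham 1, 2 and 3. With normexp background correction, or with an intensity trend and robust variance, 3 rows passed, Klk8, Neurod6 and 1 probe without a symbol (A_64_P015084), and with array quality weights 6. The filter on all 6 arrays gave 2, Klk8 and that probe, and quantile normalization, median centring and the deposited values 0. With each array centred on its median, 839 rows at an unadjusted p under 0.05 were higher and 2274 lower, 27.0% higher against 41.8% by the 75th percentile. Centring on spike-in probes gave 7145 higher and 167 lower, 97.7% higher, and 60 called rows. It moved the median of all genes from −0.04 to 0.41, and directions given here are relative to the typical gene.

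**Figure D2:**
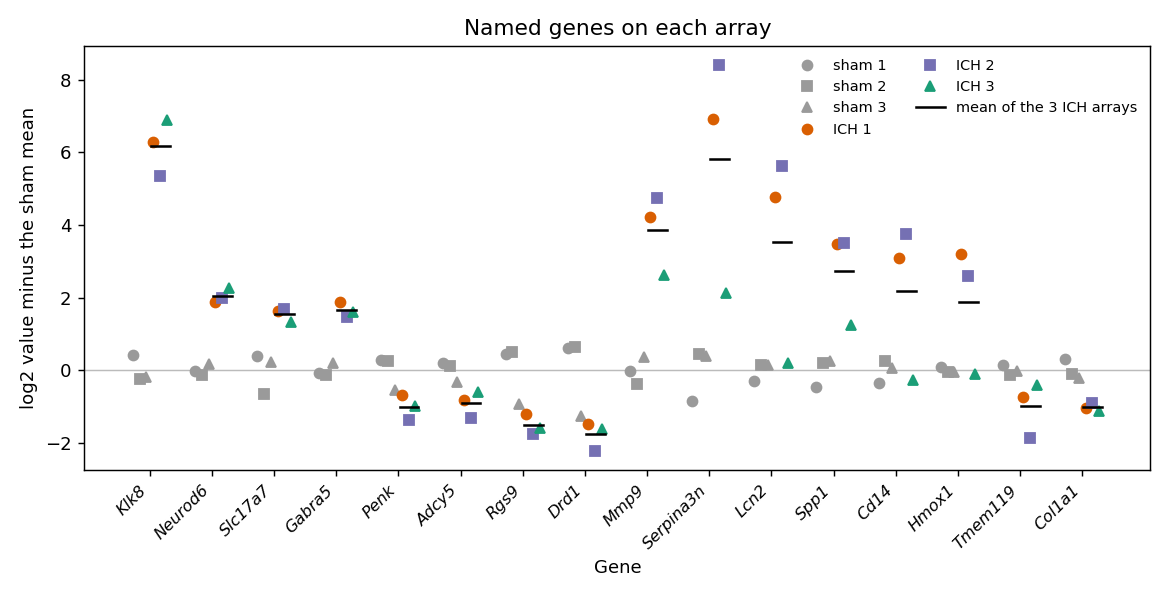
Normalized log2 value minus the sham mean for 16 genes on each array, with black bars for the mean of the 3 ICH arrays. Klk8, at 5.35 to 6.88, and Neurod6, at 1.89 to 2.27, were high on every ICH array, while Lcn2 and Cd14 stood at 0.21 and −0.26 on ICH 3 and above 3 on the other ICH arrays.

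Genes of striatal projection neurons, the main neurons of the basal ganglia, were lower as a group in ICH. Of 21 measured, 20 were lower and 8 of these passed adjusted over the list alone, with 0 passing over all genes. The D1 dopamine receptor gene Drd1 differed by −1.76 ± 0.56, Rgs9, a regulator of dopamine receptor signalling, by −1.51 ± 0.42, and the opioid precursor Penk by −1.01 ± 0.29 (adjusted p = 0.0416 for Penk adjusted over the list alone). Dlx5, Adcy5, Rasd2 and Arpp21 were also among the 8. Adcy5, the main adenylyl cyclase of the striatum, differed by −0.91 ± 0.24. The brightest members were Arpp21, at −0.64 ± 0.16, whose 2 other probes gave −0.88 and 0.28, and the phosphodiesterase gene Pde10a, at −0.85 ± 0.28. The list fell against all other genes by camera (median −0.90, adjusted p = 1.94e-06; adjusted p = 0.773 with an estimated correlation). Its median was 0.23, 0.32 and −0.55 on sham 1 to 3 and −0.72, −1.22 and −0.68 on ICH 1 to 3, so that sham 3 lay nearer to the ICH arrays than to the other sham arrays. The call held with any 1 array left out, with medians from −1.10 to −0.70.

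Cortical projection neuron markers went the other way. Of 17 measured, 12 were higher, and 7 higher and 1 lower passed adjusted over the list alone, with 0 over all genes. The 7 were the transcription factor genes Neurod6 (adjusted p = 0.000216 adjusted over the list alone), Neurod1 (1.91 ± 0.27), Neurod2 (0.90 ± 0.29) and Fezf2 (1.02 ± 0.31), the vesicular glutamate transporter gene Slc17a7 (1.55 ± 0.30), the pentraxin gene Nptx1 (1.17 ± 0.22) and Rasgrf2 (1.21 ± 0.27). The 1 lower was Cux2, a marker of upper cortical layers, at −0.76 ± 0.24. The brightest members were the neuropeptide precursor Cck, at −0.25 ± 0.15, and neurogranin (Nrgn), at 0.28 ± 0.18. Lamp5, Rorb and Ccn2, which mark cortical layers, stood at −0.03, 0.05 and 0.11, and Vip, which marks interneurons, at −0.30. The list rose by camera (median 0.28, adjusted p = 0.00364; adjusted p = 0.773 with an estimated correlation), with medians of 0.17, −0.24 and 0.12 on sham 1 to 3 and 0.21, 0.77 and 0.28 on ICH 1 to 3. Without ICH 2 the adjusted p was 0.0800, and without sham 2 the median was 0.16. With the row of the slide as a block, which leaves sham against ICH 1, the adjusted p was 0.0647, and with spike-in centring 0.0511.

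Markers of neurons in general showed no shift of this size. Of 23 measured, 12 were higher and 11 lower, with a median of 0.05 (adjusted p = 0.414, and 0.0463 with quantile normalization) that was −0.03 with median centring. Gap43, of growing axons, and the neuronal enolase gene Eno2 differed by −0.36 ± 0.16 and −0.13 ± 0.12, where another probe of Eno2 gave 0.07. Of 34 genes of glutamate and GABA signalling, 15 were higher and 19 lower, and 4 passed adjusted over the list alone, all higher: Gabra5, Slc17a7 and the NMDA receptor subunit genes Grin2a (1.31 ± 0.17) and Grin2b (0.62 ± 0.11). The GABA-B receptor gene Gabbr1, among the brightest 2, differed by −0.61 ± 0.18, where another probe of Gabbr1 gave −0.19. That list had a median of −0.02, a mean of 0.07 and an upward test (adjusted p = 0.412). Its median was 0.02 with quantile normalization and −0.07 to 0.06 with 1 array left out. With spike-in centring its median was 0.42, where that of all genes was 0.41. Thalamic neuron markers, 4 higher and 8 lower of 12, had a median of −0.05 (adjusted p = 0.781), or 0.40 with spike-in centring, near the 0.41 of all genes. Sham 1 stood at −1.07 and ICH 2 at −1.25. The list's median was −0.67 without sham 1 (adjusted p = 0.0492), and 0.19, 0.19 and 0.38 without sham 2, sham 3 and ICH 2, where the list was not called. Their brightest members, Lhx2 and the glutamate transporter gene Slc17a6, differed by 0.18 ± 0.22 and −0.74 ± 0.67.

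Several lists of inflammation genes rose by camera with the preset correlation. ICH 1 and ICH 2 lay above every sham array in most of these lists, and ICH 3 below. In the list of innate sensing, NF-kB and inflammasome genes 19 of 21 were higher (median 0.59, adjusted p = 0.00529 by camera; adjusted p = 0.773 with an estimated correlation), with medians of 0.78, 1.18 and −0.35 on ICH 1 to 3 and −0.16 to 0.18 on sham arrays. The endotoxin receptor gene Cd14 stood at 3.08, 3.75 and −0.26 on ICH 1 to 3. The only member passing adjusted over the list alone was the adhesion molecule gene Vcam1, which was lower (−0.81 ± 0.13, adjusted p = 0.0169 adjusted over the list alone). It was among the brightest 2, beside the NF-kB inhibitor gene Nfkbia, at 0.41 ± 0.30. Of 31 activated myeloid and monocyte markers 26 were higher (median 0.53, adjusted p = 0.00364; adjusted p = 0.773 with an estimated correlation), with medians of 0.80, 1.15 and −0.49 on ICH 1 to 3. Arginase (Arg1, 1.61 ± 0.29) and lipoprotein lipase (Lpl, 1.02 ± 0.20) passed adjusted over the list alone, while the brightest members, Fabp5 and Cd63, differed by −0.32 ± 0.14 and −0.03 ± 0.14. Osteopontin (Spp1) stood at 3.48, 3.50 and 1.25 on ICH 1 to 3. Of 26 reactive astrocyte markers 22 were higher (median 0.57, adjusted p = 0.00531; adjusted p = 0.773 with an estimated correlation), with medians of 0.86, 1.21 and −0.34 and 0 members passing adjusted over the list alone. The astrocyte filament gene Gfap stood at 0.91, 1.08 and −0.44, and Timp1, an inhibitor of matrix proteases, at 1.61, 2.24 and −0.34.

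Of 17 neutrophil markers 10 were higher (median 0.24, adjusted p = 0.0183; adjusted p = 0.773 with an estimated correlation), with medians of −0.37, 0.10 and 0.38 on sham 1 to 3 and 1.46, 0.21 and −0.11 on ICH 1 to 3. Cxcr1 and Mmp9 passed adjusted over the list alone. Cxcr1, a receptor for neutrophil-attracting chemokines, was well above background on 1 sham array and all ICH arrays, and stood at 5.95, 5.02 and 4.75 on ICH 1 to 3 (adjusted p = 0.163 over all genes). Of the brightest members, the protease inhibitor gene Slpi stood at 3.15, 3.69 and −0.57, and Pglyrp1 differed by 0.24 ± 0.26. The granule genes Camp and Ngp, at −0.01 and −0.75, did not go with them. Of 29 genes of matrix, proteases and fibrinolysis 21 were higher (median 0.39, adjusted p = 0.0176; adjusted p = 0.773 with an estimated correlation), with medians of 0.47, 1.13 and −0.12 on ICH 1 to 3. Mmp9 alone passed adjusted over the list alone (adjusted p = 0.0119), and Mmp3, another matrix protease not well above background on any sham array, was at least 5.82-fold higher (adjusted p = 0.301), or 9.80-fold without ICH 3 and 3.89-fold without ICH 2. The brightest, Timp2 and Timp1, differed by −0.23 ± 0.12 and 1.17 ± 0.64.

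These list calls depended on single arrays, and some other splits of the 6 arrays into groups of 3 called as many lists. The highest other split called 17 lists, against 12 for sham and ICH. Without ICH 2 the adjusted p was 0.314 for the innate sensing, myeloid, reactive astrocyte and matrix lists and 0.0643 for the neutrophil list, with medians of 0.27, 0.16, 0.22, 0.15 and 0.29. Without ICH 3 the medians of the innate sensing, myeloid and reactive astrocyte lists were 1.03, 0.96 and 1.03. Without ICH 1 they were 0.39, 0.27 and 0.37, the matrix list's median was 0.23 (adjusted p = 0.0635), and the neutrophil list's adjusted p was 0.226. The matrix list's median was 0.24 without sham 3, and the neutrophil list's 0.36, 0.16 and 0.40 without sham 1, 2 and 3. With the slide row as a block only ICH 1 is left against sham, which cannot show whether the 5 lists hold across ICH arrays. The innate sensing, myeloid, reactive astrocyte, matrix and neutrophil medians were then 0.78, 0.80, 0.86, 0.47 and 1.46. With the dimmest probes left out, on a filter of all 6 arrays, the median was 0.21 for the matrix list (adjusted p = 0.122) and 0.86 for the neutrophil list (adjusted p = 0.105). With spike-in centring none of these 5 lists was called (adjusted p from 0.320 to 0.595). The medians of the innate sensing, myeloid, reactive astrocyte, matrix and neutrophil lists were then 1.04, 0.97, 1.01, 0.84 and 0.68, where that of all genes was 0.41. Array quality weights gave medians of 0.31, 0.17, 0.30, 0.24 and 0.19 in the same order, at an adjusted p of 0.0516 to 0.0611.

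Another 4 related lists were not called, although with all arrays the cytokine list passed in 5 and the complement list in 7 of the 15 other settings. Of 32 cytokine and chemokine genes 23 were higher (median 0.42, adjusted p = 0.0576), with medians of 0.55, 1.18 and −0.49 on ICH 1 to 3. The monocyte attractant Ccl2 stood at 4.86, 5.78 and −1.34, and the brightest members, Cx3cl1 and Cxcl14, differed by −0.32 ± 0.13 and −0.40 ± 0.20. Of 19 complement genes 13 were higher (median 0.45, adjusted p = 0.0514), with 0.77, 1.07 and −0.53 on ICH 1 to 3. The receptor gene C3ar1 differed by 1.39 ± 0.52, and C1qa and C1qb, the brightest, by −0.21 ± 0.14 and −0.07 ± 0.13. Of 28 interferon-stimulated genes 21 were higher (median 0.22, adjusted p = 0.397), with 0.62, 0.80 and −0.63 on ICH 1 to 3, and the brightest, Oas1b and Mx2, differed by −0.21 ± 0.13 and −0.32 ± 0.14. Of 25 genes of heme and iron handling 15 were higher (median 0.18, adjusted p = 0.225). Hmox1, which breaks down heme, stood at 3.20, 2.60 and −0.11 on ICH 1 to 3 and the heme-binding protein gene Hpx at 1.30, 3.71 and 0.09. The brightest, ferritin light chain (Ftl1) and transferrin (Tf), differed by −0.35 ± 0.14 and −0.62 ± 0.20. Without ICH 3 all 4 passed, with an adjusted p of 6.34e-07 for cytokines, 1.55e-05 for complement, 6.55e-07 for interferon-stimulated genes and 0.0224 for heme handling. Without ICH 2 the medians were 0.04 for cytokines (adjusted p = 0.870), 0.11 for complement (adjusted p = 0.570) and −0.04 for interferon-stimulated genes (adjusted p = 0.644). Without ICH 1 they were −0.07 for interferon-stimulated genes (adjusted p = 0.835) and 0.11 for heme handling (adjusted p = 0.425). Without sham 2 the adjusted p was 0.0115 for cytokines and 0.0175 for complement, and with median centring 0.00891 and 0.0258. With the slide row as a block, which leaves sham against ICH 1, the medians were 0.62 for interferon-stimulated genes and 0.77 for complement. Array quality weights gave the cytokine, complement and interferon lists medians of 0.22, 0.11 and 0.08.

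**Figure D3:**
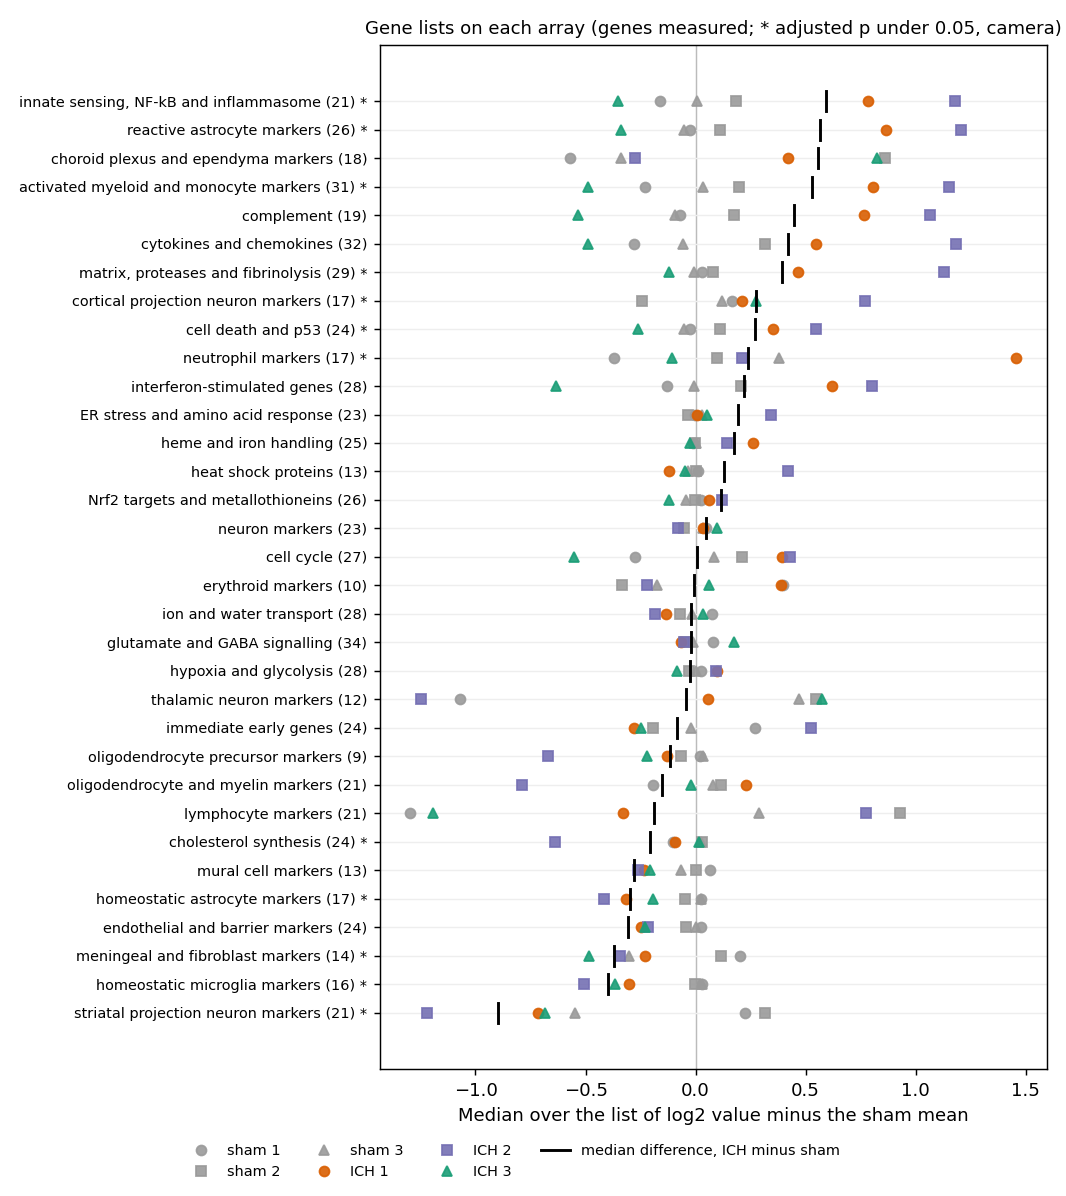
Median over each gene list of the log2 value minus the sham mean on each array, with the number of genes measured in brackets, black bars for the median difference between the groups and an asterisk for an adjusted p under 0.05 by camera. In the innate sensing list ICH 1 and ICH 2 lie at 0.78 and 1.18 and ICH 3 at −0.35, while in the striatal list ICH 1 to 3 lie at −0.72, −1.22 and −0.68. The medians of the 4 lists that fell apart from the striatal one are above 0 with spike-in centring, between 0.05 and 0.24, where that of all genes is 0.41.

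Markers of resting glia fell as groups on all 3 ICH arrays. Of 16 homeostatic microglia markers 10 were lower and 8 of these had an unadjusted p under 0.05, with 0 passing adjusted over the list alone. The purine receptor gene P2ry12 differed by −1.0 ± 0.35 and Tmem119, a marker of resident microglia, by −0.99 ± 0.38, where another probe of Tmem119 gave −0.605. Itgam, which other myeloid cells also carry, stood at 1.5, 2.47 and −0.68 on ICH 1 to 3. Aif1, among the brightest 2, differed by −0.36 ± 0.12, where another probe of Aif1 gave −0.06. The list's median was −0.40 (adjusted p = 0.0242; adjusted p = 0.773 with an estimated correlation), at −0.30, −0.51 and −0.36 on ICH 1 to 3. Of 17 homeostatic astrocyte markers 15 were lower (median −0.30, adjusted p = 0.0123; adjusted p = 0.773 with an estimated correlation), with −0.32, −0.42 and −0.19 on ICH 1 to 3 and 0 members passing adjusted over the list alone. The bicarbonate transporter gene Slc4a4 differed by −0.90 ± 0.21 and the water channel gene Aqp4 by −0.45 ± 0.13, while the glutamate transporter gene Slc1a2 differed by 0.29. Another probe of Slc4a4 gave −0.31, and other probes of Aqp4 gave −0.49 and −0.11. Aldoc and Ntsr2, the brightest, differed by −0.25 ± 0.15 and −0.29 ± 0.12. The microglia call was lost without ICH 3 (adjusted p = 0.0708) and with the slide row as a block (adjusted p = 0.144). The astrocyte call was lost without ICH 1 (adjusted p = 0.0600), with quantile normalization (adjusted p = 0.123) and with spike-in centring (adjusted p = 0.184). With spike-in centring the medians of the microglia and astrocyte lists were 0.05 and 0.15, below the 0.41 of all genes.

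Meningeal and fibroblast markers fell as a group. Of 14 measured 13 were lower (median −0.37, adjusted p = 0.0143; adjusted p = 0.773 with an estimated correlation), and the collagen genes Col1a1 (−1.01 ± 0.18) and Col1a2 (−0.62 ± 0.15) passed adjusted over the list alone. Another probe of Col1a1 gave −0.71. Decorin (Dcn) differed by 0.52, and the brightest, Ptgds and Igf2, by −0.23 ± 0.13 and −0.51 ± 0.17. The list's median was 0.20, 0.12 and −0.30 on sham 1 to 3 and −0.23, −0.34 and −0.48 on ICH 1 to 3. The call was lost without sham 2 (adjusted p = 0.0592), without ICH 3 (median −0.24, adjusted p = 0.158) and with array weights (adjusted p = 0.0838). With the slide row as a block, which leaves sham against ICH 1, the list's median was −0.23. With spike-in centring it was 0.08, below the 0.41 of all genes. Of 24 endothelial and barrier markers 15 were lower (median −0.31, adjusted p = 0.0505), at −0.25, −0.22 and −0.23 on ICH 1 to 3. The median was −0.18 without ICH 1 (adjusted p = 0.0579), and the adjusted p was 0.0165 without ICH 2, 0.210 without ICH 3, 0.0489 without sham 1 and 0.0402 with quantile normalization, and with all arrays the list passed in 6 of the 15 other settings. The drug efflux gene Abcg2 differed by −1.47 ± 0.53 and the tight junction gene Ocln by −0.60 ± 0.16, and the brightest, the glucose transporter gene Slc2a1 and the claudin gene Cldn5, by −0.01 ± 0.16 and −0.35 ± 0.14. Of 13 mural cell markers 10 were lower (median −0.28, adjusted p = 0.112). Leaving out sham 3 gave −0.37 (adjusted p = 0.0329), and leaving out ICH 2 −0.22 (adjusted p = 0.261). Myl9, a contractile protein gene, at −0.66 ± 0.15, and the receptor gene Notch3, at 0.73 ± 0.15, passed adjusted over the list alone in opposite directions, and the brightest, Tagln and Vtn, differed by −0.33 ± 0.17 and −0.39 ± 0.16.

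Of 24 cholesterol synthesis genes 20 were lower (median −0.21, adjusted p = 0.0436; adjusted p = 0.853 with an estimated correlation), with 0 passing adjusted over the list alone. The enzyme genes Cyp51, Hmgcs1 and Msmo1 differed by −0.65 ± 0.16, −0.57 ± 0.15 and −0.43 ± 0.14, the last 2 being the brightest. The list's median was −0.09, −0.64 and 0.02 on ICH 1 to 3. Without ICH 2 it was −0.01 (adjusted p = 0.899) and without ICH 3 −0.33. The call was also lost without sham 2 (adjusted p = 0.117) and sham 3 (adjusted p = 0.10), with normexp (adjusted p = 0.0671), quantile normalization (adjusted p = 0.0861), the mean of a gene's probes (adjusted p = 0.0502), the slide row as a block (adjusted p = 0.283), array weights (adjusted p = 0.234) and spike-in centring (median 0.24, adjusted p = 0.312). Of 21 oligodendrocyte and myelin markers 17 were lower (median −0.15, adjusted p = 0.225), at 0.23, −0.79 and −0.02 on ICH 1 to 3. The adjusted p was 0.0282 without ICH 1 and 0.0360 without sham 1, but the median was above 0 without ICH 2 (0.15, adjusted p = 0.565) and with the slide row as a block (0.23, adjusted p = 0.610). Mbp, among the brightest 2, differed by −1.09 ± 0.46, where another probe of Mbp gave −0.21. Of 9 oligodendrocyte precursor markers 6 were lower (median −0.11, adjusted p = 0.360), with a median of −0.45 without ICH 1 (adjusted p = 0.213) and −0.21 without ICH 2 (adjusted p = 0.314). The brightest, Bcas1 and Pdgfra, differed by −0.50 ± 0.16 and −0.06 ± 0.22. With spike-in centring the medians of the endothelial, mural, oligodendrocyte and precursor lists were 0.14, 0.17, 0.30 and 0.33, below the 0.41 of all genes.

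Of 24 genes of cell death and p53 signalling 17 were higher (median 0.27, adjusted p = 0.0313; adjusted p = 0.773 with an estimated correlation). Bid, which links death receptors to mitochondria, passed adjusted over the list alone (1.47 ± 0.23, adjusted p = 0.0156) and was high on every ICH array, at 1.90, 1.38 and 1.12. The brightest members did not go with it: the survival gene Bcl2l1 differed by −0.50 ± 0.15, where 1 of its 3 other probes gave 0.65, and Bax by −0.0049 ± 0.14. The list's median was 0.35, 0.55 and −0.26 on ICH 1 to 3. Without ICH 2 it was 0.05 (adjusted p = 0.565) and without ICH 3 0.48. The call was also lost without sham 3 (adjusted p = 0.10) and ICH 1 (adjusted p = 0.0936), with array weights (adjusted p = 0.130) and with spike-in centring (adjusted p = 0.428).

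The other stress and signalling lists were not called. Of 23 genes of ER stress and the amino acid response 15 were higher (median 0.19, adjusted p = 0.0514). The folding factor gene Creld2 differed by 1.11 ± 0.37 and the transcription factor gene Cebpb by 0.81 ± 0.23, and the brightest, Hsp90b1 and Atf4, by 0.03 ± 0.11 and −0.23 ± 0.13. The adjusted p was 0.0412 without ICH 1, 0.0497 without ICH 3 and 0.0426 without sham 3, and with all arrays the list passed in 7 of the 15 other settings. Its median was 0.02 without ICH 2 (adjusted p = 0.314) and 0.0068 with the slide row as a block (adjusted p = 0.618). Of 26 Nrf2 targets and metallothioneins 15 were higher (median 0.11, adjusted p = 0.360, but −0.0043 without ICH 2), and the antioxidant genes Sod1 and Gpx4, the brightest, differed by −0.29 ± 0.13 and −0.24 ± 0.14. Of 13 heat shock protein genes 8 were higher (median 0.13, adjusted p = 0.412), with a median of −0.10 without ICH 2 and −0.12 with the slide row as a block. Hspb1 stood at 2.31, 2.88 and −0.02 on ICH 1 to 3, and Hspa8 and Hspe1, the brightest, differed by −0.18 ± 0.12 and −0.04 ± 0.16, where 2 of the 3 other probes of Hspa8 gave 0.44 and 0.46. The hypoxia and glycolysis list, 13 higher and 15 lower of 28, had a median of −0.03, a mean of 0.01 and an upward test (adjusted p = 0.807), and its brightest, Gapdh and Eno1, differed by −0.16 ± 0.12 and −0.20 ± 0.12. The immediate early gene list, 10 higher and 14 lower of 24, had a median of −0.09, or −0.24 to 0.05 with 1 array left out, a mean of 0.10 and an upward test (adjusted p = 0.397). In that list Nr4a3, Dusp5 and Myc stood at 1.11, 1.07 and 1.31 and Egr2 and Egr4 at −0.98 and −0.88, and the brightest, Arc and Dusp6, differed by −0.36 ± 0.24 and 0.34 ± 0.14. Of 27 cell cycle genes 14 were higher (median 0.01, adjusted p = 0.397), with Pcna and Kif20a, the brightest, at 0.19 ± 0.16 and −0.09 ± 0.18. Its median was 0.40 without ICH 3 (adjusted p = 0.00032), and −0.16, −0.09 and −0.09 without ICH 1, ICH 2 and sham 1. It was 0.39 with the slide row as a block, which leaves sham against ICH 1. Of 28 genes of ion and water transport 14 were higher (median −0.02, adjusted p = 0.944). Aqp4, among the brightest 2, stood at −0.45 ± 0.13, where other probes of it gave −0.49 and −0.11. With spike-in centring the median was above 0 in every list of this paragraph, but that of all genes was then 0.41. The hypoxia and ion transport lists had medians of 0.04 and 0.01 with quantile normalization. In the cell cycle list the median was −0.05 with quantile normalization, −0.07 with median centring and −0.01 with the deposited values. Quantile normalization gave an adjusted p of 0.011 for ER stress, 0.0415 for Nrf2 targets and 0.0463 for heat shock proteins.

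Markers of blood and of the ventricle lining varied as much among sham as among ICH arrays. Lymphocyte markers, 6 higher and 15 lower of 21, had a median of −0.19 (adjusted p = 0.772), at −1.30, 0.93 and 0.29 on sham 1 to 3 and −0.33, 0.78 and −1.20 on ICH 1 to 3. It was −0.68 without sham 1 (adjusted p = 0.0102), and 0.21, 0.11 and 0.19 without sham 2, sham 3 and ICH 3, where the list was not called. Nkg7 and Zap70, the brightest, differed by −0.19 ± 0.61 and −0.02 ± 0.40. Erythroid markers, 5 higher and 5 lower of 10, had a median of −0.01, or −0.15 to 0.16 with 1 array left out, a mean of 0.21 and an upward test (adjusted p = 0.576). The beta-globin genes Hbb-b1 and Hbb, the brightest, differed by 1.26 ± 0.36 and 0.65 ± 0.31, where a second probe of Hbb gave 2.42, and Alas2, of heme synthesis in red cell precursors, stood at 2.90, 1.5 and 0.81 on ICH 1 to 3 and 0.85 on sham 1. Of 18 choroid plexus and ependyma markers 12 were higher (median 0.56, adjusted p = 0.225), at −0.57, 0.86 and −0.34 on sham 1 to 3 and 0.42, −0.27 and 0.83 on ICH 1 to 3. The median was 0.82 without sham 2 (adjusted p = 0.00105), 0.11 without sham 1 (adjusted p = 0.790) and 0.10 with the filter on all 6 arrays (adjusted p = 0.60). Transthyretin (Ttr) and Drc12, the brightest, differed by 0.16 ± 0.47 and −0.39 ± 0.15. With spike-in centring the medians of the lymphocyte and erythroid lists were 0.26 and 0.44, where that of all genes was 0.41. The lymphocyte list was then called as lower than other genes (adjusted p = 0.0160). Array quality weights gave the lymphocyte list −0.69 (adjusted p = 0.0516).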

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

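Spike-in centring, array quality weights and every count at an unadjusted p under 0.05 were chosen only after the result was seen. With all arrays, limma called 0 genes and camera 12 lists, and the cause of the changes below was not tested unless stated. All 12 lists kept their direction by camera in every setting. Normexp called 3 genes and lost cholesterol synthesis (adjusted p = 0.0671); the filter on all 6 arrays called 2 genes and lost the matrix (adjusted p = 0.122) and neutrophil lists (0.105); trend and robust variance called 3 genes. All of these were higher and at least 2-fold. Quantile normalization lost cholesterol synthesis (0.0861) and homeostatic astrocytes (0.123), and the mean of a gene's probes lost cholesterol synthesis (0.0502). Median centring gave 839 genes higher at an unadjusted p under 0.05. The slide row as a block, which by construction compares sham with ICH 1, lost cholesterol synthesis (0.283), cortical neurons (0.0647), homeostatic microglia (0.144) and meninges (0.169). Spike-in centring called 60 genes, all higher and at least 2-fold, with 7312 at an unadjusted p under 0.05 (7145 higher, 167 lower), and 4 lists; it lost innate sensing (0.485), matrix (0.320), cell death (0.428), cholesterol synthesis (0.312), cortical neurons (0.0511), homeostatic astrocytes (0.184), reactive astrocytes (0.595), activated myeloid cells (0.480) and neutrophils (0.595). Array quality weights, 0.159 for ICH 2 and 4.35 for sham 3, called 6 genes, all higher and at least 2-fold, and 5 lists, and lost innate sensing (0.0587), matrix (0.0555), cell death (0.130), cholesterol synthesis (0.234), reactive astrocytes (0.0516), activated myeloid cells (0.0611), neutrophils (0.0555) and meninges (0.0838). An estimated correlation called 0 lists, with 0.773 for each of the 12 except cholesterol synthesis (0.853). Fry called 0 lists, with 0.756 for innate sensing, 0.692 for matrix and cholesterol synthesis, 0.694 for cell death, reactive astrocytes and activated myeloid cells, 0.258 for striatal and 0.111 for cortical neurons, 0.0799 for homeostatic astrocytes and microglia, 0.395 for neutrophils and 0.365 for meninges. Lists not called before were gained in several settings with all arrays: 6 with quantile normalization, 4 each with median centring, the deposited values and no filter on dim probes, 3 each with normexp, the replicate block and the slide row, and 1 each with the filter on all 6 arrays, the mean of a gene's probes, spike-in centring and array weights. ER stress and complement were gained in 7 of 15 such settings, endothelium in 6 and cytokines in 5. Leaving out 1 array at a time, called genes ran from 0 to 36 (0 to 32 higher, 0 to 4 lower, 0 to 36 at least 2-fold), genes at an unadjusted p under 0.05 from 1346 to 4688 (683 to 2135 higher, 663 to 2553 lower) and called lists from 5 to 16. The adjusted p ran from 3.52e-10 to 0.314 for innate sensing and for reactive astrocytes, 5.67e-06 to 0.314 for matrix, 0.000283 to 0.565 for cell death, 0.00386 to 0.899 for cholesterol synthesis, 0.000402 to 0.0800 for cortical neurons, 0.00855 to 0.0600 for homeostatic astrocytes, 0.0137 to 0.0708 for homeostatic microglia, 1.94e-10 to 0.314 for activated myeloid cells, 0.000448 to 0.226 for neutrophils and 0.000317 to 0.158 for meninges. The replicate numbers did not pair the arrays (correlations of deviations −0.19, −0.008 and 0.0696), and the replicate block called 0 genes, with 2409 at an unadjusted p under 0.05, and kept all 12 lists. Outlier spots kept, the deposited values and no filter on dim probes called 0 genes and kept all 12 lists, the last 2 with the gains above. Slide or scan as a block was not run, as all arrays share 1 of each.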

Other observations

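The tests of neuron loss, scaling, a wrong label, slide row and blood cells were chosen only after the result was seen, while the hippocampal list and the splits of the arrays were set before. Spike-in probes were dimmer against the 75th percentile on every ICH array, at 1.33, 1.09 and 1.45 on ICH 1 to 3, than on the sham arrays, at 1.80, 1.74 and 1.65. The arrays alone do not show whether the amount of spike-in or of RNA differed, so no direction for all genes together was drawn from them.

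Striatal markers were lower and cortical projection neuron markers higher on the ICH arrays. A loss of neurons of every kind would lower the general neuron markers, whose median was 0.0458. Over quantile, median and spike-in scaling the highest striatal median was −0.452, with spike-in centring, where all genes had 0.41. Median and spike-in centring shift all genes of an array alike, so they could not bring the striatal median to that of all genes. Quantile normalization could, and it gave a striatal median of −0.80, where all genes had −0.02. As a hypothesis, a different share of brain regions in the dissected tissue, with more hippocampus and less striatum, may underlie the pattern: of 16 hippocampal markers 12 were higher, with a median of 0.28 on the log2 scale, at 0.18, 0.19 and 0.30 on ICH 1 to 3 and 0.03, −0.11 and 0.09 on sham 1 to 3. By camera that list passed with the preset correlation between genes and not with an estimated one, and members at an unadjusted p under 0.05 included Trpc6 (0.90) and Zbtb20 (0.39). A loss of striatal neurons next to the hematoma, a biological explanation, was not tested and stays open.

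Medians of several inflammation lists were high on ICH 1 and ICH 2 and at or below the sham level on ICH 3, whose activated myeloid and reactive astrocyte medians, −0.49 and −0.34, lay under every sham array, while single genes such as Serpina3n (2.14) and Cxcl2 (1.43) stayed above the sham arrays on it. The slide row as the cause would leave ICH 1 at the level of the sham arrays in its row, but its activated myeloid median lay 0.605 above the highest of them, where the sham arrays spanned 0.430, and ICH 2 and ICH 3, which share a row, stood at 1.15 and −0.49. As a hypothesis, cells entering from blood may be fewer on ICH 3, but this stays open: of 17 neutrophil markers 8 were above every sham array on ICH 1 and ICH 2, of which 5 were not so on ICH 3 and 3, among them Cxcr1 at 4.75, were. For a wrong label, an array with tissue like that of the sham arrays, 22% of 100 genes chosen without ICH 3 lay nearer the ICH mean on it, against 84 and 67 for ICH 1 and ICH 2 and 15, 23 and 26 for the sham arrays, each on genes chosen without that array, while on genes chosen without ICH 3 and 1 sham array the counts were 24, 28 and 27 of 100 on ICH 3 against 14, 9 and 8 on that sham array, and 135, 136 and 164 of 500 against 34, 58 and 46. Of the 36 genes or probes called without ICH 3, 17 lay beyond every sham array on it in the same direction. Among them were Klk8 at 6.88, A_64_P015084 at 3.17 and Neurod6 at 2.27. The 36 were chosen on these same sham arrays, so no chance share can be set beside the 17. On genes chosen without ICH 3 and 1 sham array, more lay nearer the ICH mean on ICH 3 than on that sham array. ICH 3 shares its slide row with ICH 2 and with no sham array, so these counts cannot tell tissue from place on the slide. The first comparison put ICH 3 within the sham arrays, but there the sham counts used an ICH mean that held ICH 3. A wrong label was not excluded, and whether the sample came from further off the hematoma was not tested.

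The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05. All 10 gave 0 genes at an adjusted p under 0.05, and all 10 gave 0 at least 2-fold, the highest other being 0 in each case. At an unadjusted p under 0.05 only 1 of the 10, the real one, gave as many as 3265 genes, the highest other giving 1202. For lists called by camera 5 of the 10 gave as many as the real 12, and the highest, 17, was the split of sham 1, ICH 1 and ICH 2 from the other arrays.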
